A study of Mus musculus with 12 samples.

How the data were processed

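RNA from 12 sorted CD4+ T cell samples of mouse Peyer's patches was hybridised to Affymetrix mouse gene arrays, 3 for each of 4 groups. Per the labels' protocols, cells negative for class II and Epcam were sorted by GFP, CXCR5 and PD-1, and cDNA was made from total RNA with a whole-transcript kit and hybridised after fragmentation. The authors deposited 1 table of log2 expression values for 34760 probe sets, made with RMA in the oligo package per the submitters' processing notes. RMA subtracts a background, makes the arrays' distributions alike and summarises probes on a log scale, so low signals are compressed, differences of genes with a group below the array median (6.34 to 6.45) can be understated, and a shift of most genes at once is removed. The genome build is not given in the sources used here, and no coordinates are printed. All 12 columns were named for their sample, and 0 were left unmapped.

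Groups follow the sample titles, which also give the replicate numbers 1 to 3. Probe sets were named from the platform annotation, with symbols updated through the RefSeq gene table of assembly GRCm38.p6. Of the probe sets 21640 had 1 gene symbol (21553 matched by gene identifier, 87 kept the older symbol), 1321 had several and 11799 were unnamed here; the last 2 kinds name no gene in the text. For the 953 genes with more than 1 probe set, that with the highest mean over the 12 arrays was used, which gave 19937 genes. A gene was tested if it lay above the array's median of all probe sets on at least 3 arrays, which left 11240 genes and took out 8697.

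Each of 5 comparisons was a contrast in 1 linear model of all 12 arrays (limma 3.58.1 in R 4.3.3, lmFit and eBayes), with 8 residual degrees of freedom and 11.5 in total after moderation, and Benjamini-Hochberg adjustment over the genes tested at 0.05. All groups share 1 estimate of the spread. The SE of a difference is the moderated one. The 22 gene lists were written before the data were examined, as were the tests, the rule for named genes and the alternatives not said to be added later. Lists were tested with camera at a preset correlation of 0.01, which compares a list with all other genes, and adjusted over lists within a comparison; an estimated correlation and fry were alternatives.

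The genes named are, per comparison, the sort markers and the highest and lowest log2 differences among genes past the threshold whose replicates do not overlap, 8 each way for the first and second comparisons and 5 for the others. Where fewer passed, those with the smallest p fill the number. Of each fixed list up to 4 members with the smallest p may be named, and for lists described in the text 1 to 4 of these are printed. Of the genes named, Cetn4, Crybg1, Gtpbp10, Minpp1 and Set had more than 1 probe set, and the mean of a gene's probe sets, an alternative added for named genes after seeing the data, changed no call of a named gene; with it Set did not pass the filter. Slc17a9, the 1 Tfh program gene that fell, is outside this rule and was named after its values were seen, as were Ikzf2 and Ctla4 in GFP+ over GFP- Tfh. Predicted genes, microRNA, small nucleolar RNA and receptor segments are skipped.

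The code was tested on simulated data with the real genes' spread and the 4 groups' own widths, in 10 draws per comparison with 200 of 11240 genes changed. For GFP+ over GFP- Tfh it recovered 80.9% of genes changed by 1 log2 unit and 98.2% of those changed by 2; for CXCR5+PD1- over CXCR5-PD1- it recovered 78.8% and 98.0%. False genes among those called were 23.5% for GFP+ over GFP- Tfh and 21.2% for GFP+ Tfh over CXCR5-PD1-, and 0.767% to 1.26% for the other comparisons, because the shared spread is too small for the GFP+ arrays and too large for the rest. With 1 weight per group the share was 4.64% to 5.88%. The simulation drew independent noise with 1 width per group, which is what that fit assumes. It cannot show how that fit does on the real arrays.

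Samples with the same replicate number were checked for deviating together. In CXCR5+PD1- over CXCR5-PD1- the correlations of their deviations from the group means were 0.210 to 0.353, all above 0.1. In the other 4 comparisons at least 1 pair lay below 0.1, which does not show that pairing is absent there. The labels do not say what the numbers mark, so they entered the fit only in alternatives. Alternatives changed the filter, moderation, weights, normalisation, groups in the fit, block and probe set rule and left out each replicate in turn; 1 weight per group, sex as a block and the male arrays alone were added after seeing the data. A planned test of a CXCR5+ gene set in the GFP comparison was not run, since 0 genes passed to make the set.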

Results

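Gene expression was measured on 12 Affymetrix mouse gene arrays, each hybridised with RNA from CD4+ T cells sorted from Peyer's patches, the lymphoid follicles of the small intestine. The mice carried a bacterial artificial chromosome in which enhanced green fluorescent protein (GFP) reports the gene for interleukin 21, a cytokine by which T cells help B cells. The 12 arrays fell into 4 groups of 3. T follicular helper (Tfh) cells, sorted by the chemokine receptor CXCR5 and the receptor PD-1, were split into GFP+ and GFP- cells, and the other groups were GFP- cells that were CXCR5+PD1- or CXCR5-PD1-. Values are log2 expression, given as mean ± SD with n = 3, and differences are given ± SE. A total of 11240 genes were tested. The labels do not say whether replicates came from separate animals, so p-values measure the spread between these samples, and the number of arrays limits the precision.

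The sort markers separated the Tfh gates from both PD1- gates. Il21 stood at 10.60 ± 0.31 in GFP+ Tfh, 9.96 ± 0.34 in GFP- Tfh, 6.50 ± 1.11 in CXCR5+PD1- cells and 6.64 ± 1.09 in CXCR5-PD1- cells. Cxcr5 stood at 8.95 ± 0.29, 8.21 ± 0.36, 5.61 ± 0.37 and 5.71 ± 0.43 in the same order. Pdcd1, the gene for PD-1, stood at 9.02 ± 0.67, 9.11 ± 0.34, 7.09 ± 0.20 and 6.87 ± 0.06. The characteristics of the GFP+ arrays give them as CXCR5- and PD1- while their titles and the sorting protocol give CXCR5+ and PD1+. The groups here follow the titles, and Cxcr5 and Pdcd1 in all 3 GFP+ arrays lay above all 6 PD1- arrays. Epcam and the class II genes H2-Aa and H2-Ab1, whose proteins were gated out, did not pass the filter on low values, and H2-Eb1 stood at 6.62 to 6.71 in the 4 groups. Xist, the RNA of the inactive X chromosome, stood at 10.7 to 11.3 in replicate 3 of each group and at 4.87 to 5.49 in replicates 1 and 2. The Y-linked Eif2s3y stood at 3.70 to 4.04 and 8.59 to 9.30, so replicate 3 was female and replicates 1 and 2 male in each group.

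**Figure D1:**
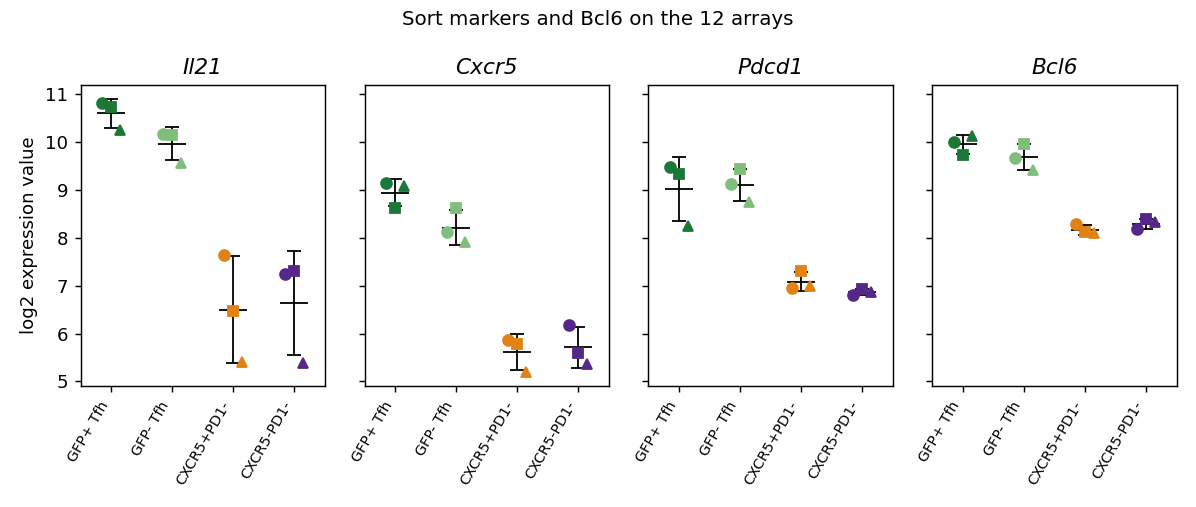
Log2 expression values of Il21, Cxcr5, Pdcd1 and Bcl6 (vertical axis) in the 4 groups (horizontal axis); circles, squares and triangles are replicates 1, 2 and 3, and bars are the mean ± SD. For all 4 genes every Tfh array lies above every PD1- array, and mean Cxcr5 is 5.61 in CXCR5+PD1- and 5.71 in CXCR5-PD1- cells.

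The first comparison, which the stated aim of the series names, set GFP+ Tfh against GFP- Tfh. Il2ra, the alpha chain of the interleukin 2 receptor, fell by 2.72 ± 0.28 on the log2 scale, from 8.55 ± 0.17 in GFP- to 5.83 ± 0.70 in GFP+ cells (adjusted p = 0.00451). Itm2a, which encodes a membrane protein of activated T cells, fell by 2.22 ± 0.24 (adjusted p = 0.00475). St8sia6, a sialyltransferase gene, fell by 1.27 ± 0.15 (adjusted p = 0.00734). Adamts6, a metalloproteinase gene, fell by 1.23 ± 0.13 (adjusted p = 0.00451), and Ppp3ca, a catalytic subunit of calcineurin, fell by 0.80 ± 0.11 (adjusted p = 0.0285). These were the 5 genes past adjusted p 0.05 in limma, each lower in all 3 GFP+ arrays than in any GFP- array, and 0 genes were higher. In GFP+ Tfh all 5 lay below the array median, at 5.83, 5.60, 5.73, 5.92 and 6.31, where differences are compressed, so their falls can be larger than measured. At an unadjusted p under 0.05, 214 genes were higher and 614 lower with the shared spread, and 461 in all differed with 1 weight per group, where chance gives 562. The median difference was 0.034 with no filter, -0.018 with the filter used and -0.076 with a stricter one at the 70th percentile. Better expressed genes thus read lower as a set, which can add to the excess of lower genes and lower lists. With cyclic loess on top 4 genes passed, all lower.

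The genes of the gate itself did not pass in this comparison. Il21 differed by 0.63 ± 0.56 (adjusted p = 0.824), Cxcr5 by 0.74 ± 0.26 (adjusted p = 0.561), Pdcd1 by -0.08 ± 0.28 and Cd4 by 0.20 ± 0.14. Il21, Cxcr5 and Cd4 were higher in every GFP+ array than in any GFP- array, and Pdcd1 was not. Of all genes tested 8.74% did not overlap between these groups. The SD of Il21 was 0.31 in GFP+ and 0.34 in GFP- Tfh, and its SE rests on the spread shared with the more variable PD1- arrays. Over its alternatives the limma adjusted p of Il21 was 0.634 or more. Of the 25 measured genes of the Tfh program, 0 passed, with a median difference of 0.04, and the list was not called, except as higher without GFP- replicate 2 or GFP+ replicate 3. Among them Bcl6, the lineage-defining repressor of Tfh cells, differed by 0.26 ± 0.15, Maf by 0.32 ± 0.23 and Il4 by -1.06 ± 0.69. The higher genes with the smallest p, none past the threshold, were Ndufb3 (0.83 ± 0.14), Minpp1 (0.86 ± 0.16, or 0.28 ± 0.14 with the mean of its 2 probe sets), Slc35a3 (0.67 ± 0.14), Senp5 (0.53 ± 0.11), Ccdc90b (1.29 ± 0.29), Dera (0.71 ± 0.16), Armc7 (0.74 ± 0.18) and Mtif2 (0.42 ± 0.10). The next lower genes, which also did not pass, were Anapc1 (-0.70 ± 0.11), Rab23 (-1.30 ± 0.22) and Myo1e (-1.26 ± 0.22). Myo1e passed with sex as a block (limma adjusted p = 0.0425) and with the replicate block. Anapc1, Rab23, Senp5, Ndufb3, Armc7 and Minpp1 also passed in at least 1 alternative (lowest limma adjusted p 0.0175 for Anapc1 to 0.0451 for Minpp1).

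**Figure D2:**
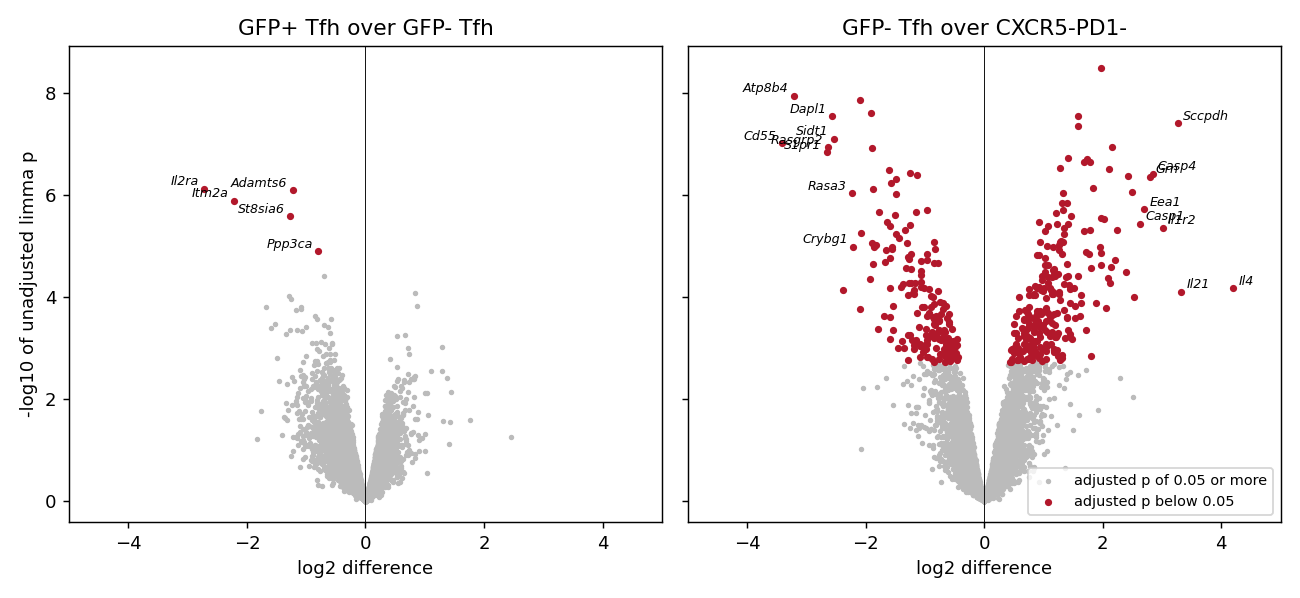
Each point is 1 of 11240 genes, with its log2 difference (horizontal axis) against the -log10 of its unadjusted limma p (vertical axis), for GFP+ over GFP- Tfh (left) and GFP- Tfh over CXCR5-PD1- cells (right). Red points, 5 on the left and 429 on the right, have an adjusted p below 0.05, and the labelled genes are the highest and lowest differences among them.

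Camera called 6 of the 22 fixed lists in this comparison, all lower in GFP+ Tfh, and 0 held with an estimated correlation; fry called the regulatory and trafficking lists (adjusted p = 0.0372 and 0.00798). In the regulatory T cell list 1 of 15 measured members fell over all genes and 6 fell when adjusted over the list alone (camera adjusted p = 1.64e-05; adjusted p = 0.178 with an estimated correlation). Beside Il2ra, its members with the smallest p were Itgae, the integrin alpha E chain, at -1.34 ± 0.28, the cytokine gene Il10 at -1.09 ± 0.30 and Foxp3, the regulator that defines regulatory T cells, at -0.64 ± 0.18. The trafficking list had 0 of 19 members past the threshold and 3 lower over the list alone (camera adjusted p = 0.00165; adjusted p = 0.0777 with an estimated correlation), among them Gpr18 at -0.88 ± 0.22 and Ccr7 at -0.74 ± 0.20. The Th1 and cytotoxic list had 0 of 15 past it and 1 lower over the list alone (camera adjusted p = 0.00165; adjusted p = 0.200 with an estimated correlation), with Eomes at -0.60 ± 0.16, Il18r1 at -1.30 ± 0.46, Cxcr6 at -0.60 ± 0.22 and Nkg7 at -0.50 ± 0.20.

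The 3 other called lists were cytokines, naive and recirculating cells and Th2. Each had 0 members past the threshold over all genes and 2, 2 and 1 lower when adjusted over the list alone (camera adjusted p = 0.0150, 0.0150 and 0.0250; adjusted p = 0.300, 0.668 and 0.178 with an estimated correlation). Of their members, Csf1 differed by -0.83 ± 0.19, Il7r by -1.67 ± 0.30, S1pr1 by -0.55 ± 0.24, Il17rb by -0.64 ± 0.19 and Ccr4 by -0.77 ± 0.29, and none of these 5 passed. On leaving out replicates, the naive list lost its call without GFP+ replicate 1 or 2 or GFP- replicate 3 and the Th1 list without GFP+ replicate 1. The Th2 list lost it without GFP+ replicate 1 or 3 or GFP- replicate 1, and the cytokine list without GFP+ replicate 3 or GFP- replicate 1. Cyclic loess also ended the call of the naive list. Cell cycle genes were not called, with Birc5 at -0.52 ± 0.14 and Ccnb2 at -0.57 ± 0.16, except as lower with no filter and without GFP+ replicate 1 or GFP- replicate 3. The neighbours of Il21 in the genome were not called, with Spata5 at -0.50 ± 0.20. Of the myeloid markers Lyz2 differed by 1.38 ± 0.38 and did not pass. The 6 lists for other cell types (B cells, germinal centre B and plasma cells, myeloid, epithelial, stromal, and CD8, NK and gamma delta T cells) were not called on the members that passed the filter, nor with no filter. Over all members on the array, 3 of these 6 lists had median levels that did not overlap between the groups, where chance gives 10%. Relative to the array median, the 11 germinal centre B and plasma cell genes lay at -0.02, -0.08 and 0.11 in GFP+ Tfh and at -0.46, -0.22 and -0.41 in GFP- Tfh. The 20 myeloid genes lay at -0.31, -0.25 and -0.21 against -0.38, -0.54 and -0.52, and the 16 epithelial genes at -1.06, -0.93 and -0.66 against -1.06, -1.09 and -1.11, where the nearest pair is equal at this rounding. Median, mean and test differed in sign for 8 uncalled lists: immediate early, interferon and stress genes and those of the other cell types except B cells.

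The GFP+ arrays were the most variable, with a root mean square deviation from their group mean of 0.342, 0.287 and 0.405 against 0.163 to 0.204 in the other arrays. Simulated data with that spread and 200 of 11240 genes changed gave 23.5% false genes among those called for this comparison. The real comparison called 5 genes, so the simulation does not give the false share among these. With 1 weight per group, an alternative chosen after seeing the data, Il2ra, Itm2a and Adamts6 passed and St8sia6 and Ppp3ca did not. The simulated share with that fit was 5.88%. The simulation drew 1 width per group, as that fit assumes, so the share cannot show how it does on the real GFP+ arrays. The count was 95 (14 higher, 81 lower) with a weight per array. In that fit GFP+ replicates 1 to 3 had weights of 0.266, 1.87 and 0.226, so the GFP+ mean rested mostly on replicate 2. The count was 0 with the 2 groups alone (471 at an unadjusted p under 0.05) and 0 with the male arrays (616 unadjusted). Without GFP+ replicate 1 it was 237 (15 higher, 222 lower), and without GFP+ replicate 2 it was 5 (1 higher, 4 lower). Without GFP- replicate 1 it was 3, where the adjusted p of St8sia6 was 0.0700. Ppp3ca lost its call without any 1 of the replicates but GFP+ replicate 1 (highest adjusted p 0.241), and with sex as a block (adjusted p = 0.0535; 0.0136 to 0.752 over its 15 alternatives).

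**Figure D3:**
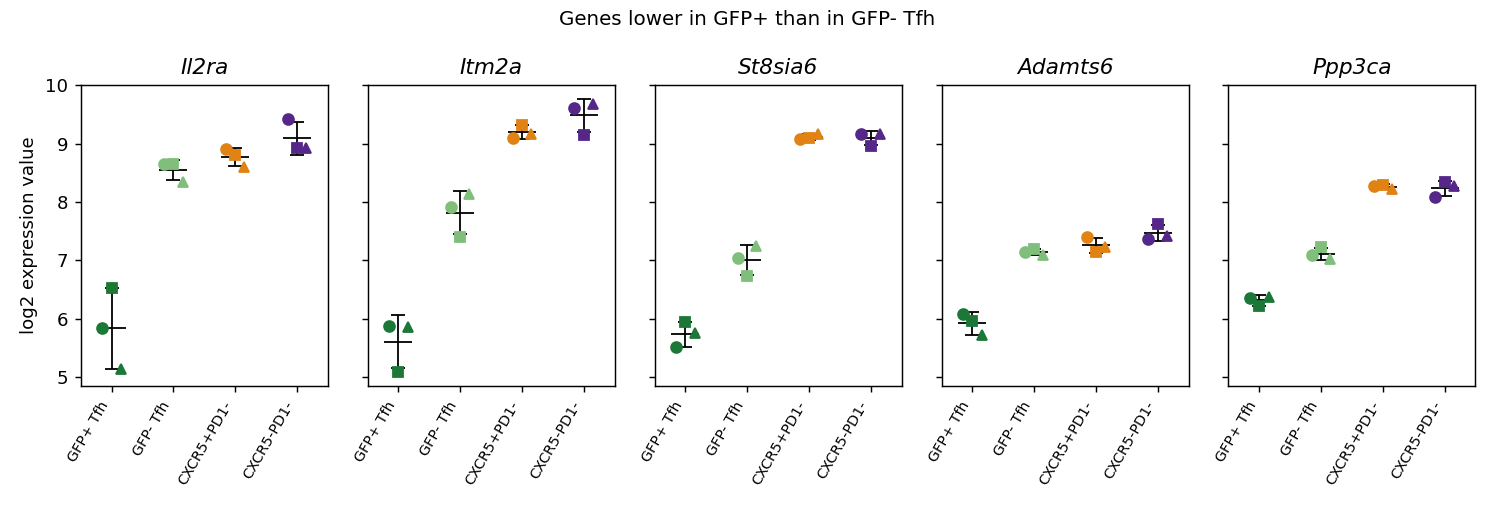
Log2 expression values (vertical axis) of the 5 genes that fell in GFP+ against GFP- Tfh, in the 4 groups (horizontal axis); circles, squares and triangles are replicates 1, 2 and 3, and bars are the mean ± SD. Mean Il2ra is 5.83 in GFP+ Tfh and 8.55 in GFP- Tfh.

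GFP- Tfh were next compared with CXCR5-PD1- cells. The cytokine genes Il4 and Il21 rose by 4.20 ± 0.69 and 3.32 ± 0.56, Cxcr5 by 2.50 ± 0.26 and Pdcd1 by 2.23 ± 0.28 (n = 3 per group), while Cd4 differed by 0.40 ± 0.14 and did not pass. Cd55, which restrains complement, fell by 3.41 ± 0.29, and S1pr1, the receptor by which lymphocytes leave lymphoid organs, fell by 2.66 ± 0.24. Limma called 429 genes, 249 higher and 180 lower. In 79 of them the lower group lay below the array median, where differences are compressed. Among these were Cxcr5, Il4, Cd55, Sccpdh, Il1r2, Casp1, Atp8b4 and Dapl1, so their order by size is that of the measured values only.

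The other genes with the highest differences were Sccpdh (3.26 ± 0.26), the interleukin 1 decoy receptor gene Il1r2 (3.01 ± 0.37), the inflammatory caspase genes Casp4 (2.84 ± 0.28) and Casp1 (2.63 ± 0.32), the progranulin gene Grn (2.79 ± 0.28) and the endosomal gene Eea1 (2.70 ± 0.31). The others with the lowest differences were Atp8b4 (-3.21 ± 0.23), Rasgrp2 (-2.63 ± 0.23), Dapl1 (-2.56 ± 0.20), Sidt1 (-2.54 ± 0.21), Rasa3 (-2.24 ± 0.24) and Crybg1 (-2.20 ± 0.30, or -1.06 ± 0.18 with the mean of its 2 probe sets). A total of 1 small nucleolar RNA was skipped among the lower genes.

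Of 25 Tfh program genes, 13 rose and 1, Slc17a9, fell (21 and 1 adjusted over the list alone; camera adjusted p = 7.31e-21; adjusted p = 0.00419 with an estimated correlation). Tnfsf8 rose by 2.11 ± 0.20, the signalling adaptor gene Sh2d1a by 1.74 ± 0.16, Bcl6 by 1.39 ± 0.15 and the costimulatory receptor gene Icos by 1.32 ± 0.15. Of 18 genes of naive and recirculating cells, 13 fell and 0 rose (16 and 0 over the list alone; camera adjusted p = 2.99e-25; adjusted p = 0.00765 with an estimated correlation), among them Igfbp4 by -1.91 ± 0.14 and the lymph node homing receptor Ccr7 by -1.78 ± 0.20. Of 9 coinhibitory genes 6 rose (9 over the list alone; camera adjusted p = 6.91e-13; adjusted p = 0.0274 with an estimated correlation), including Tigit by 2.13 ± 0.32, Nt5e by 1.96 ± 0.27, Ctla4 by 1.03 ± 0.16 and Cd274 by 0.76 ± 0.13.

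The cell cycle, cytokine, Th17, Th2 and glycolysis lists were called by camera with the preset correlation and not with an estimated one, with 3 of 21, 3 of 17, 2 of 9, 1 of 6 and 1 of 12 members higher and 5, 5, 3, 3 and 4 over the list alone. Their camera adjusted p was 0.000620, 0.00352, 0.00482, 0.0121 and 0.0177, and the adjusted p with an estimated correlation was 0.438, 0.190, 0.200, 0.0996 and 0.474. Fry called the cytokine, Th17 and Th2 lists (adjusted p = 0.0274, 0.0366 and 0.00793) but not cell cycle and glycolysis (0.139 for both). Their members that rose included Kif11 (1.05 ± 0.21), Mcm6 (1.05 ± 0.23), Birc5 (0.57 ± 0.14), Csf1 (0.82 ± 0.19), Ahr (0.85 ± 0.19), Rora (0.78 ± 0.19) and Pfkp (0.76 ± 0.14). Immediate early genes of T cell receptor signalling went both ways and were not called, 4 up and 1 down of 22 (5 and 3 over the list alone), with Nfatc1 at 1.16 ± 0.16, Tnfrsf9 at 0.95 ± 0.21, Egr2 at 0.65 ± 0.15 and Nr4a1 at -0.76 ± 0.16. Among trafficking genes, called lower by fry (adjusted p = 0.0138) but not by camera (adjusted p = 0.383), 2 rose and 5 fell of 19 (6 and 5 over the list alone), with the integrin gene Itgal at 1.32 ± 0.18 and Itgb7 at -0.96 ± 0.13. Ikzf2 of the regulatory list rose by 1.71 ± 0.24, Hmox1 of the stress list rose by 1.19 ± 0.18, Cd8b1 fell by 0.82 ± 0.19, and Cetn4, a neighbour of Il21, differed by 1.92 ± 0.69 without passing. No list for another cell type was called, except the CD8, NK and gamma delta list with no filter and the myeloid list without CXCR5-PD1- replicate 3. Over all members on the array, 2 of these 6 lists did not overlap between the groups, where chance gives 10%: relative to the array median, CD8, NK and gamma delta genes lay at -0.90 to -0.66 in GFP- Tfh and -0.46 to -0.29 in CXCR5-PD1- cells, and epithelial genes at -1.11 to -1.06 and -1.03 to -0.95. The stress list was called with no filter, with cyclic loess and without CXCR5-PD1- replicate 1 or 3 or GFP- replicate 2. The regulatory list was called with no filter and without CXCR5-PD1- replicate 1, and the Th1 list without CXCR5-PD1- replicate 3. The cytokine list lost its call without GFP- replicate 1, and the glycolysis list without GFP- replicate 2 or CXCR5-PD1- replicate 2. Median, mean and test differed in sign for the immediate early, regulatory and CD8, NK and gamma delta lists, none of them called.

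The count moved to 791 with 1 weight per group, 665 with the 2 groups alone and 912 with a weight per array. It was 266 with the male arrays, 280 and 237 without GFP- Tfh replicates 1 and 2 and 261 and 228 without CXCR5-PD1- replicates 2 and 3. Nr4a1, Tnfrsf9, Egr2, Ahr, Rora, Kif11, Mcm6, Birc5, Csf1 and Cd8b1 each lost the call without at least 4 of the 6 replicates in turn (highest adjusted p 0.0656 for Kif11 to 0.184 for Rora).

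GFP+ Tfh were compared with the same CXCR5-PD1- arrays. Il21 rose by 3.96 ± 0.56, Sccpdh by 3.85 ± 0.26, Cxcr5 by 3.23 ± 0.26, Il4 by 3.14 ± 0.69 and Il1r2 by 3.08 ± 0.37 (n = 3 per group), and Pdcd1 and Cd4 rose by 2.15 ± 0.28 and 0.60 ± 0.14. The lowest differences were Cd55 (-3.99 ± 0.29), Itm2a (-3.88 ± 0.24), St8sia6 (-3.37 ± 0.15), the interleukin 7 receptor gene Il7r (-3.27 ± 0.30) and Il2ra (-3.26 ± 0.28). Limma called 697 genes, 275 higher and 422 lower, and in 128 of them the lower group lay below the array median, as in Cxcr5, Sccpdh, Il4, Il1r2, Cd55, Itm2a, St8sia6 and Il2ra.

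Of the Tfh program 15 genes rose and 1, Slc17a9, fell of 25 (21 and 1 over the list alone; camera adjusted p = 6.3e-19; adjusted p = 0.0059 with an estimated correlation), with Sh2d1a at 1.78 ± 0.16 and Bcl6 at 1.66 ± 0.15. Of the naive and recirculating genes 15 of 18 fell (17 over the list alone; camera adjusted p = 2.94e-22; adjusted p = 0.0115 with an estimated correlation), with S1pr1 at -3.21 ± 0.24 and Ccr7 at -2.52 ± 0.20. Of the coinhibitory genes 6 of 9 rose, and 9 over the list alone, with Tigit at 2.15 ± 0.32 and Ctla4 at 1.06 ± 0.16 (camera adjusted p = 1.01e-09; adjusted p = 0.0587 with an estimated correlation). Among trafficking genes 3 rose and 6 fell of 19 (4 and 10 over the list alone), with Gpr18 at -1.98 ± 0.22 (camera adjusted p = 0.0101; adjusted p = 0.0587 with an estimated correlation). The Th1 and cytotoxic list had 2 of 15 lower, Il18r1 at -2.07 ± 0.46 and Prf1 at -0.70 ± 0.17, and 3 over the list alone (camera adjusted p = 0.00297; adjusted p = 0.204 with an estimated correlation), and the Th17 list had 1 of 9 higher, Ccr6 at 0.89 ± 0.24, and 1 over the list alone (camera adjusted p = 0.0343; adjusted p = 0.39 with an estimated correlation). Fry called these lists except Th17 (adjusted p = 0.106).

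Lists that were not called held single genes that changed, among them 3 up and 3 down of 22 immediate early genes, 2 up and 2 down of 15 regulatory genes and 2 down of 14 sterol synthesis genes. Nfatc1 rose by 1.39 ± 0.16 while Myc fell by 2.58 ± 0.53 and Nr4a1 fell by 1.17 ± 0.16. Foxp3 fell by 0.92 ± 0.18 while Ikzf2 rose by 1.80 ± 0.24. The sterol synthesis genes Nsdhl and Hmgcs1 fell by 1.89 ± 0.30 and 0.96 ± 0.21. Mcm6, which loads on replication origins, rose by 1.39 ± 0.23, Hmox1 by 1.24 ± 0.18, Gadd45b by 0.71 ± 0.18 and the B cell gene Pax5 by 0.47 ± 0.10. The stress list was called with cyclic loess and without CXCR5-PD1- replicate 1 or 3 or GFP+ replicate 2, the regulatory list with no filter and without CXCR5-PD1- replicate 3, the cell cycle list with no filter and without GFP+ replicate 3, and the glycolysis list without GFP+ replicate 3. The Th17 list lost its call with no filter, with cyclic loess and without GFP+ replicate 1 or 2 or CXCR5-PD1- replicate 3. Over all members on the array, CD8, NK and gamma delta genes lay at -0.71 to -0.68 in GFP+ Tfh and -0.46 to -0.29 in CXCR5-PD1- cells relative to the array median, the 1 of 6 lists for other cell types that did not overlap, where chance gives 10%. Median, mean and test differed in sign for the uncalled Th2, cytokine, sterol, B cell, stromal and CD8, NK and gamma delta lists.

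With 1 weight per group 314 genes passed, of which 313 were among the 697, and Cd4, Prf1, Foxp3, Hmgcs1, Gadd45b, Pax5 and Ccr6 did not. The false share in simulated data for this comparison, with 200 of 11240 genes changed, was 21.2% with the shared spread and 4.64% with these weights. The simulation drew 1 width per group, as these weights assume, so the 4.64% cannot be carried over to the real arrays. The count was 255 with the 2 groups alone, 1411 with a weight per array and 392 with the male arrays (228 higher, 164 lower). The GFP+ mean behind the 1411 rested mostly on GFP+ replicate 2, with a weight of 1.87 against 0.266 and 0.226. Without GFP+ replicate 1 the count was 1147 (332 higher, 815 lower), and without GFP+ replicate 3 it was 411 higher and 384 lower. The count was 438 without CXCR5-PD1- replicate 2 and 348 without CXCR5-PD1- replicate 3. Cd4, Il4, Myc, Il18r1, Prf1, Hmgcs1, Gadd45b, Pax5 and Ccr6 lost the call without 1 or more of the 6 replicates in turn (highest adjusted p 0.0579 for Hmgcs1 to 0.162 for Ccr6).

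CXCR5+PD1- cells were compared with CXCR5-PD1- cells. Cxcr5 itself differed by -0.10 ± 0.26, Il21 by -0.14 ± 0.56, Pdcd1 by 0.21 ± 0.28 and Cd4 by -0.07 ± 0.14. Mean Cxcr5 lay below the array median in both groups, where differences are compressed. Limma called 0 genes, and at an unadjusted p under 0.05 it gave 137, 72 higher and 65 lower, with the shared spread, 162 with the replicate block, 404 with 1 weight per group and 406 with the 2 groups alone, where chance gives 562. Each of these fits called 0 genes. The higher genes with the smallest p, none past the threshold, were Gtpbp10 (1.06 ± 0.22, or 0.29 ± 0.27 with the mean of its 2 probe sets), Tmem109 (0.47 ± 0.11), Paxip1 (0.43 ± 0.10), Sprtn (0.56 ± 0.15) and Slc25a27 (0.58 ± 0.16). The lower ones were Set (-1.54 ± 0.32), Sf3b6 (-0.50 ± 0.11), Ube2g1 (-0.46 ± 0.11), Cog1 (-0.60 ± 0.15) and Klhdc3 (-0.56 ± 0.16). The medians of the Tfh program and of the naive and recirculating list were -0.06 and -0.03, with Sh2d1a at 0.15 ± 0.16 and Igfbp4 at -0.25 ± 0.14. Nsdhl of sterol synthesis differed by -0.87 ± 0.30 and Cd8b1 by -0.57 ± 0.19, and 0 of the 22 lists were called. Median, mean and test differed in sign for the Th2, regulatory, cell cycle and CD8, NK and gamma delta lists. Without CXCR5-PD1- replicate 3 camera called 4 lists lower (coinhibitory, Th1 and cytotoxic, regulatory and myeloid), and the naive and recirculating list was called lower without CXCR5-PD1- replicate 1 or CXCR5+PD1- replicate 3. The sorting protocol in the labels does not describe the CXCR5+PD1- gate.

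GFP- Tfh were last compared with CXCR5+PD1- cells. Il4 rose by 3.78 ± 0.69, Il21 by 3.46 ± 0.56, Grn by 2.92 ± 0.28, Sccpdh by 2.90 ± 0.26 and the proenkephalin gene Penk by 2.70 ± 0.36 (n = 3 per group). Cxcr5 and Pdcd1 rose by 2.60 ± 0.26 and 2.02 ± 0.28. The lowest differences were Atp8b4 (-3.58 ± 0.23), Cd55 (-3.21 ± 0.29), S1pr1 (-2.64 ± 0.24), Dapl1 (-2.57 ± 0.20) and Sidt1 (-2.45 ± 0.21), with 1 small nucleolar RNA skipped. Limma called 422 genes, 262 higher and 160 lower, and in 64 of them the lower group lay below the array median, as in Il4, Sccpdh, Cxcr5, Atp8b4, Cd55 and Dapl1.

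Of 25 Tfh program genes 14 rose and 0 fell (19 and 1 over the list alone; camera adjusted p = 8.92e-22; adjusted p = 0.0036 with an estimated correlation), with Tnfsf8 at 2.07 ± 0.20, Sh2d1a at 1.59 ± 0.16, Bcl6 at 1.52 ± 0.15 and Tox at 1.43 ± 0.17. Of 18 naive and recirculating genes 11 fell (15 over the list alone; camera adjusted p = 8.92e-22; adjusted p = 0.0126 with an estimated correlation), with Igfbp4 at -1.66 ± 0.14 and Ccr7 at -1.64 ± 0.20. Of 9 coinhibitory genes 6 rose (9 over the list alone; camera adjusted p = 9.46e-14; adjusted p = 0.0225 with an estimated correlation), with Tigit at 2.34 ± 0.32 and Nt5e at 2.12 ± 0.27. The cell cycle, cytokine, Th17, Th2, regulatory, glycolysis and stress lists were called by camera with the preset correlation and not with an estimated one, with 1 of 21, 3 of 17, 1 of 9, 1 of 6, 2 of 15, 1 of 12 and 1 of 12 members higher and 7, 5, 2, 3, 4, 4 and 2 over the list alone. Their camera adjusted p was 0.000268, 0.000821, 0.00375, 0.00535, 0.0212, 0.0212 and 0.0282 (adjusted p = 0.385, 0.124, 0.185, 0.0677, 0.413, 0.413 and 0.579 with an estimated correlation). Fry called the cytokine, Th17 and Th2 lists (adjusted p = 0.0289, 0.0408 and 0.00518) but not the other 4, and called the trafficking list lower (adjusted p = 0.0104), which camera did not (adjusted p = 0.348). The regulatory list was called upward while its median was -0.01 and its mean 0.35, and its Ikzf2 rose by 1.94 ± 0.24. Ccnb2 rose by 0.66 ± 0.16, Hmox1 by 0.88 ± 0.18 and Cxcl13 by 0.56 ± 0.12, and Ifit2 fell by 0.64 ± 0.15. The stress list lost its call without GFP- replicate 1 or 3 or CXCR5+PD1- replicate 2, the glycolysis list without GFP- replicate 2 or CXCR5+PD1- replicate 2, and the regulatory list without GFP- replicate 3. The sterol list was called with no filter and without GFP- replicate 3, and the immediate early list with no filter. Of the lists for other cell types, over all members on the array, 1 of 6 did not overlap, where chance gives 10%: stromal genes lay at 0.01 to 0.16 in GFP- Tfh and -0.13 to -0.10 in CXCR5+PD1- cells. Median, mean and test also differed in sign for the uncalled interferon and B cell lists.

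The count was 843 with 1 weight per group, 776 with the 2 groups alone and 1042 with a weight per array. It was 266 with the male arrays, 233 and 232 without GFP- Tfh replicates 1 and 2 and 280, 231 and 214 without CXCR5+PD1- replicates 1, 2 and 3. Ifit2, Cxcl13, Ccnb2 and Hmox1 lost the call without at least 3 of the 6 replicates in turn (highest adjusted p 0.0934 for Hmox1 to 0.193 for Ccnb2).

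**Figure D4:**
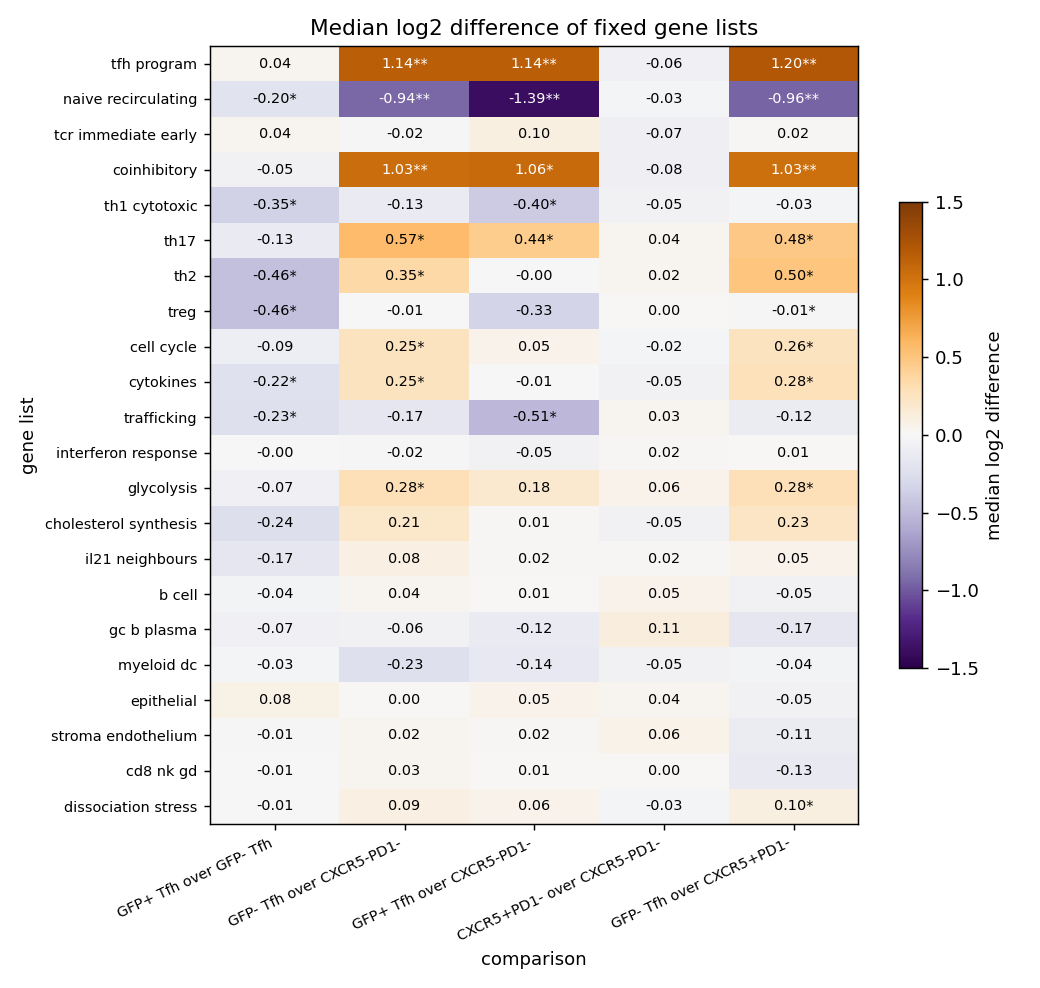
Median log2 difference over the measured members of each of 22 fixed gene lists (vertical axis) in the 5 comparisons (horizontal axis), in colour and as numbers; * marks lists called by camera and ** those that also held with an estimated correlation. The Tfh program reads 1.14 in both Tfh comparisons with CXCR5-PD1- cells and 0.04 between GFP+ and GFP- Tfh.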

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

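The tests of the GFP+ and CXCR5+ patterns below were chosen after the results were seen; the counts over other splits of the samples were planned before. Probe sets outside the gene comparisons, with no gene name here or several, drew attention because some of the 7008 above the filter differed between groups in limma: 2 in GFP+ over GFP- Tfh, 13 in GFP- Tfh over CXCR5-PD1-, 65 in GFP+ Tfh over CXCR5-PD1- and 15 in GFP- Tfh over CXCR5+PD1-.

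Il2ra, Itm2a, St8sia6, Adamts6 and Ppp3ca were lower in GFP+ than in GFP- Tfh. Wider spread of the GFP+ arrays stays open for all of these genes. Il2ra, Itm2a and Adamts6 kept their calls with 1 weight per group, with a largest limma adjusted p of 0.0255. The fit cannot decide for them, because these 3 genes were grouped by having passed it. With the 2 groups alone limma called 0 genes. The highest limma adjusted p over the 15 alternatives was 0.258 for each of the 3 genes (lowest for Il2ra 0.000491). St8sia6 and Ppp3ca lost their calls with 1 weight per group, where their smaller limma adjusted p was 0.0555 (for St8sia6 0.00681 to 0.397 over its alternatives). Their differences were -1.27 ± 0.19 and -0.80 ± 0.14, against an SE of 0.15 and 0.11 before, so the calls ended through a larger SE. CXCR5-PD1- cells in the GFP- gate would have to make up 65.1% and 69.7% of it to give Il2ra and Adamts6. The 15 naive and recirculating genes that fell in GFP+ Tfh over CXCR5-PD1- then all lay above the predicted fall. Their medians above it were 0.864 ± 0.185 and 0.925 ± 0.190, which argues against shares that large. The smaller shares of Itm2a (26.5%, median 0.214 ± 0.131), Ppp3ca (26.5%, 0.213 ± 0.131) and St8sia6 (15.2%, 0.0436 ± 0.117) stay open, with 14, 14 and 10 of the 15 genes above the predicted fall. Each ± of a median is an SE over the 15 genes, taken as independent, and not between arrays. The list's estimated correlation was 0.218 and the error of the share is left out, so each ± can be too narrow. Fewer Foxp3+ regulatory cells in the GFP+ gate stay open as a source of the fall. Ppp3ca differed from Foxp3 by -0.158 ± 0.209. Il2ra, Itm2a, St8sia6 and Adamts6 fell further than Foxp3, by differences of -2.08 ± 0.33, -1.58 ± 0.30, -0.63 ± 0.23 and -0.589 ± 0.219. Each ± against Foxp3 takes the 2 genes as independent, though both were read on the same arrays. It also rests on the shared spread, which is too small for the GFP+ arrays. The comparison cannot decide, because the background of the Foxp3 probe set, which read 7.03 in GFP+ Tfh, is not known here. Of the 15 regulatory list members 12 were lower in GFP+ Tfh and 3 higher. Ikzf2 and Ctla4 were among the higher ones, each by less than its SE, so neither shows a rise from GFP- to GFP+ Tfh. Over CXCR5-PD1- cells Ikzf2 rose by 1.80 ± 0.24 in GFP+ Tfh and by 1.71 ± 0.24 in GFP- Tfh. Ctla4 rose by 1.06 ± 0.16 in GFP+ Tfh and by 1.03 ± 0.16 in GFP- Tfh over the same cells.

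No gene passed between CXCR5+PD1- and CXCR5-PD1- cells. Too few arrays is argued against for changes as large as those of GFP- Tfh. The 95% intervals of 97.9% of the 429 genes called in GFP- Tfh over CXCR5-PD1- excluded that change. These genes were chosen for a large change in the same fit, which can overstate it and makes exclusion easier. Their median difference was 5.11% of that change, and 271 shared its sign. Both differences subtract the same CXCR5-PD1- arrays, so shared error can give such signs and such a ratio without any change. Smaller changes stay open. Whether both gates hold the same kind of cells, by the sort or by the labels, stays open. The Cxcr5 difference was -0.101 (95% interval -0.68 to 0.48). Cxcr5 read 5.61 in CXCR5+PD1- and 5.71 in CXCR5-PD1- cells, below array medians of 6.44 and 6.41, where differences are compressed. The same gene read 8.21 in GFP- Tfh, so a rise of that size would have shown. CXCR5 protein was not measured here, and a difference in protein without one in RNA stays open.

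GFP+ Tfh arrays varied more than the other groups. Each correlated best with an array outside its own group, at 0.970, 0.944 and 0.897 for replicates 1 to 3. Their highest correlations with another GFP+ array were 0.933, 0.933 and 0.880. Xist and the Y-linked genes Eif2s3y, Uty and Kdm5d put the arrays numbered 3 of all 4 groups as female and the others as male. Sex as the whole cause is argued against, since the female GFP+ array deviated 1.98 times as far as the largest of the other female arrays. A single deviating array is argued against as well: the highest correlation of a pair of GFP+ arrays was 0.933, below the lowest of the other groups, 0.963. The yield of a small gate may be the source and was not tested.

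The splits of 6 arrays into groups of 3 number 10, too few for a share under 0.05. The real count and the highest of the other splits were 5 and 0 in GFP+ over GFP- Tfh (1 of 10 splits as large), 429 and 0 in GFP- Tfh over CXCR5-PD1-, 697 and 0 in GFP+ Tfh over CXCR5-PD1-, 422 and 0 in GFP- Tfh over CXCR5+PD1- (1 of 10 each) and 0 and 0 in CXCR5+PD1- over CXCR5-PD1- (10 of 10), where limma gave 137 genes at an unadjusted p under 0.05 with the shared spread and 404 with 1 weight per group.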

How the results depend on the processing

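The fits with 1 weight per group, with sex as a block and on the male arrays, and for named genes with the mean of the probe sets, were chosen after seeing the data. In the order GFP+ over GFP- Tfh, GFP- Tfh over CXCR5-PD1-, GFP+ Tfh over CXCR5-PD1- and GFP- Tfh over CXCR5+PD1-, where limma called 5, 429, 697 and 422 genes, a weight per array gave 95, 912, 1411 and 1042, the 2 groups alone 0, 665, 255 and 776, 1 weight per group 3, 791, 314 and 843, and the male arrays 0, 266, 392 and 266; the 0 for the 2 groups alone and for the male arrays had 471 and 616 genes at an unadjusted p under 0.05. With a weight per array the GFP+ mean behind the 95 and 1411 rested mostly on GFP+ replicate 2. A log2 difference of at least 1 as well left 226, 339 and 223 in the last 3 comparisons. Leaving out 1 replicate gave 3 to 237, 228 to 326, 348 to 1147 and 214 to 319, with fewer samples in the fit. The rise to 237 and 1147 came without GFP+ replicate 1, and its cause was not tested. That array correlated best with an array outside its group (0.970, against at most 0.933 with a GFP+ array). With an estimated correlation 0, 3, 2 and 3 lists were called in place of 6, 8, 6 and 10, and fry, which does not compare a list with other genes, gave 2, 7, 5 and 7, of which 2, 6, 5 and 6 were among camera's. In CXCR5+PD1- over CXCR5-PD1- every limma fit run gave 0 genes (57 to 498 at an unadjusted p under 0.05), and lists called ranged from 0 to 4 on leaving out 1 replicate. The replicate block gave 6, 544, 814, 0 and 498 genes over the 5 comparisons, all within 1.5 times. It ended the calls of Ppp3ca, Birc5 and Ccnb2 and made that of Myo1e. All correlations of paired deviations lay above 0.1 only in CXCR5+PD1- over CXCR5-PD1-. Elsewhere 5, 4, 3 and 6 of 6 samples (in the order above) correlated best with their own number, a hint from the data and not the design. Replicate 3 was female in all 4 groups, so the numbers may mark a shared source in every group. The labels do not say, and the main fit leaves the numbers out. Sex as a block gave 5, 508, 759, 0 and 481 genes and the same lists; of the reported genes it ended the call of Ppp3ca and made that of Myo1e. Of 2444 refits of 163 reported gene differences, 2284 kept their side of the threshold, 142 lost and 18 gained it and 0 reversed a call, while 10 that did not pass changed sign; 29 of the 107 that passed lost the call somewhere. Other choices of filter, moderation, normalisation and probe set kept counts within 1.5 times. The test of CXCR5+ genes in the GFP comparison and its alternatives were not run, since no gene made the set. Genes near the array median are limited by signal over background.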
